A study of Mus musculus with 70 samples.

How the data were processed

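The series holds 70 samples of mouse CD8 T cells. Processed files were analysed for 5 of its groups. In B6/Cast F1 mice these are CBFβ ChIP-seq of naive cells (4 samples) and of day 7 cells (5 samples), T-bet ChIP-seq at day 7 (2 samples) and Eomes ChIP-seq at day 7 (3 samples), each with 1 background sample. In B6/Spret F1 mice it is 1 single-cell RNA-seq library at day 7. Samples were grouped by strain, cell state, time point and antibody as the labels give them. Per the labels, each replicate of a ChIP group and its background name the same peak list, so the lists hold no values per replicate. How the authors combined replicates and set thresholds is not stated.

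Per the submitters' processing notes, STAR 2.5.0c, Picard 1.141 and MACS2 2.1.1 were used with the build GRCm38, without a statement of which tool made which file. The peak lists have the column layout of MACS2 narrowPeak output, and the units below follow from that layout and from the values. The authors' peak score, as deposited, is a whole number up to 1000 of unstated formula. The deposited enrichment is the fold over background that the peak caller gives. Significance was deposited by the authors as −log10 p and −log10 q for each peak. The deposited summit is an offset in bp from the start of the peak. The lowest scores were 541 and 542 in the CBFβ lists of naive and day 7 cells, 159 for T-bet and 417 for Eomes. The single-cell table was deposited by the authors as whole-number UMI counts per cell and gene, without normalisation. Its library was made with the Chromium Single Cell 3' kit per the labels, and how cells were selected is not stated.

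Before the data were examined, the comparisons, their tests, the filters, the gene lists, the cell type markers, most alternatives and a rule for named genes were fixed. The rule named the members of the fixed lists, the genes of the 10 most significant peaks of each list, the 5 genes with most naive only and with most day 7 only CBFβ peaks, and the 5 with most peaks of T-bet and not Eomes and of the reverse. For single cells it named the 10 highest and the 10 lowest ratios among genes with at least 200 UMIs whose interval excluded 1, list members with at least 50 UMIs, and 5 leading genes per cluster. Genes outside this rule, and genes picked for the plots, were chosen after their values were seen.

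Peaks were called shared when they overlapped by at least 1 bp. Shares have 95% Wilson intervals, which cover counting error only. Chance overlap came from 100 random placements of each list within its chromosomes. The share of day 7 CBFβ peaks with a T-bet or Eomes peak was compared between peaks that were and were not in the naive list by Fisher's exact test, two-sided, adjusted by the Benjamini-Hochberg method over 20 tests. As 56.3% of the day 7 CBFβ peaks tie at the score of 1000, strength was taken into account in 4 equal bins of −log10 q, a change made after the data were seen. Odds ratios were pooled over the bins by the Mantel-Haenszel method.

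A peak was assigned to the protein-coding gene on chromosomes 1 to 19 whose span lay nearest to its summit, within 50 kb, and to every gene whose span held it. The plan named transcription start sites, but the annotation used gives no strand, so gene spans were used. Whether a summit lies in an exon or an intron is not known from spans. Of the peaks, 96.3% were assigned for naive CBFβ, 95.1% for day 7 CBFβ, 90.2% for T-bet and 87.6% for Eomes. Each of 14 gene lists was tested in each peak list by Fisher's exact test, two-sided, against the 20665 genes that could take a peak, adjusted over 56 tests. Of 240 list symbols, 236 were on these chromosomes. Some genes belong to several lists, so tests of different lists are not independent. Members with a peak in one list only were compared by an exact McNemar test, adjusted over 13 lists, which was chosen after the counts were seen. The planned motif shares were not computed because no genome sequence was at hand, and the planned allelic counts because the files hold no counts per parental allele.

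Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, 2766 of 2920. Of these, 5 had at least 3 markers of another cell type and at most 1 UMI over 6 T cell receptor genes. They were set aside by a rule chosen after the data were seen. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering at a resolution of 0.6. A cluster was called low-cycling when its level of cycling genes was below 0.25 of that of all cells. Klrg1 cells had a Klrg1 UMI and no Il7r UMI, and Il7r cells the reverse. Counts were summed over each group and divided by the group's total UMIs to give CPM. Ratios of summed counts have exact conditional 95% intervals, which cover counting error only. No test was made, since the library is 1 sample. Medians of gene lists and of peak classes were ranked among 10000 random lists matched on expression. Of 240 list symbols, 224 had a column.

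The alternatives tried were another overlap rule, summits within 200 bp, the stronger 50% of peaks, equal numbers of peaks, distances of 10 and 100 kb, a background of genes with at least 10 UMIs, random lists matched on locus size, other cell filters, cells thinned to 1500 UMIs, no cycling clusters, at least 2 UMIs of the marker, and other clusterings. A minimum enrichment of 2-fold, the bins of −log10 q, peaks over 1 kb from gene ends, lists without Eomes peaks over 5 kb and peak classes without cycling clusters were added after the data were seen. The methods were tested on simulated data. Simulated counts had no spread between cells, and random genes were drawn without regard to locus size or expression. The checks therefore do not cover these features of the real data. The overlap of lists matched a brute-force count at all 3654 peaks, the gene list test called 0.0714% of 1400 tests with random genes and 100% of planted lists, the ratio intervals held the true ratio in 95.8% of 2000 draws, and the pooled odds ratio was 2.02 for a true value of 2. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9 and matplotlib 3.10.9.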

Results

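The series followed CD8 T cells of mice, most of them hybrids, through infection with lymphocytic choriomeningitis virus (LCMV), with cells from the spleen labelled naive, day 7 or day 60. Its 70 samples comprise 29 for bulk RNA-seq, 22 for ATAC-seq, 1 for single-cell RNA-seq and 18 for ChIP-seq. The hybrids are crosses of C57BL/6 (B6) with the wild-derived strains Cast or Spret, so that each of their cells carries the genomes of both parents. Some bulk RNA-seq samples are labelled as B6 or Cast cells from a source named BMC F1. The ChIP-seq samples came from B6/Cast F1 mice and targeted 3 transcription factors. CBFβ, the partner subunit shared by the RUNX factors, was profiled in 4 naive and 5 day 7 samples. T-bet, the product of Tbx21, was profiled in 2 day 7 samples, and Eomes, its close relative, in 3. Each of these 4 groups also had 1 background sample. The data analysed here are 1 peak list for each of the 4 ChIP-seq groups and the cell-by-gene count table of the single-cell library, which came from B6/Spret F1 mice at day 7. The ATAC-seq and bulk RNA-seq samples, including all day 60 samples, were not analysed here.

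The CBFβ list held 4923 peaks in naive cells and 11340 at day 7, the T-bet list 3654 and the Eomes list 3519. All lay on chromosomes 1 to 19. Median enrichment over background, as the authors' peak caller gave it, was 5.62-fold for naive CBFβ, 6.65-fold for day 7 CBFβ, 3.45-fold for T-bet and 5.11-fold for Eomes. Each group has 1 list, so no value from the lists has a spread between replicates, and the read depth of the ChIP libraries is unknown. Intervals cover counting error only. The single-cell table held 2920 cells and 10349747 UMIs, with 303 to 23139 UMIs per cell and a median of 2925.5.

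The first comparison asked how binding of CBFβ differed between naive and day 7 cells. Most peaks of the naive list were also in the longer day 7 list, while most day 7 peaks were absent from the naive list. Of the 4923 naive peaks, 4551 overlapped a day 7 peak (92.4%, 95% Wilson interval 91.7 to 93.1). In the other direction, 4537 of the 11340 day 7 peaks overlapped a naive peak (40.0%, 39.1 to 40.9), leaving 6803 that were in the day 7 list only. Random placement of the peaks within chromosomes gave mean shares of 1.24% and 0.560%. Where naive and day 7 peaks overlapped, their summits lay a median of 25 bp apart. Day 7 peaks that were also in the naive list were stronger, with a median enrichment of 8.38-fold against 5.92-fold for day 7 only peaks. They also lay more often within 1 kb of the end of a gene span (60.4%, 59.0 to 61.8, against 36.4%, 35.3 to 37.6). The lists differ in length, and with the day 7 list reduced to its 4923 most significant peaks, 65.2% of naive peaks overlapped a day 7 peak, down from 92.4%. The reverse was then 64.8%, close to it because lists of equal length overlap nearly one to one.

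**Figure D1:**
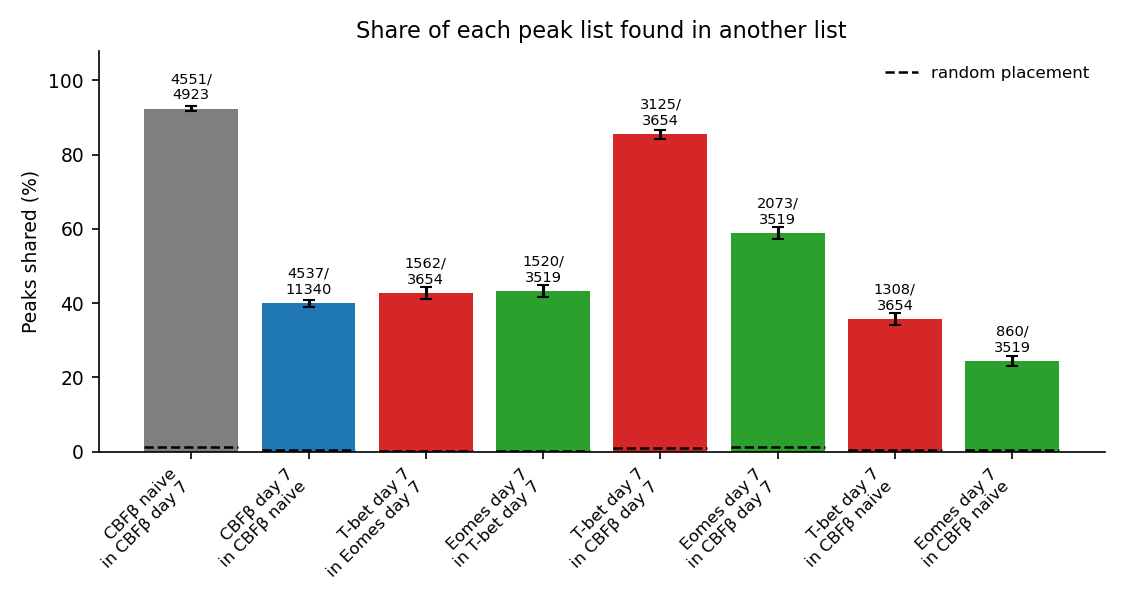
Share of the peaks of each list that overlap a peak of another list, in percent, with 95% Wilson intervals. Numbers above the bars are shared peaks over all peaks, and the dashed lines mark the mean share under random placement, which is at most 1.25%.

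Genes of several fixed lists, the effector lists among them, gained CBFβ peaks at day 7. The 17 genes of the effector molecule list, which include those of granzymes, perforin, cytokines and chemokines, held 8 CBFβ peaks in naive cells and 44 at day 7. The 18 terminal effector genes held 6 and 44. Ifng, the gene of interferon gamma (GRCm38 chromosome 10, 118441046 to 118445894), went from 1 peak to 9. Gzmb, which encodes granzyme B (chromosome 14, 56258836 to 56262334), had 0 peaks in the naive list and 5 at day 7. Klrg1, the surface receptor that marks terminal effector cells, had 0 and 5, and Cx3cr1, a chemokine receptor of effector cells, had 0 and 3. No naive peak near these genes was absent from day 7. Of the effector molecules, 9 had a CBFβ peak at day 7 and not in naive cells and 0 the reverse (exact McNemar test, two-sided, p = 0.00391, adjusted p = 0.0127 over 13 lists). For terminal effector genes the counts were 12 and 0 (exact p = 0.000488, adjusted p = 0.00317). The exact test also passed for T cell transcription factors (12 and 0, adjusted p = 0.00317), trafficking genes (9 and 0, 0.0127), interferon response genes and cell cycle genes (8 and 0 each, 0.0169) and inhibitory receptors (7 and 0, 0.0290). Some lists share members, so these results are not independent. Zeb2, Tbx21 and Id2 count for both terminal effector genes and transcription factors. Cx3cr1, S1pr5 and Itgb1 count for both terminal effector and trafficking genes. Over all protein-coding genes the occupied share went from 19.97% to 36.4%, and no test set the effector lists apart from that difference. The McNemar test was chosen after the counts were seen, and it does not correct for the greater length of the day 7 list.

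Genes of naive and memory cells were occupied at both times. The memory and naive list held 52 CBFβ peaks in naive cells and 66 at day 7, and 12 of the 52 were in the naive list only. Tcf7, which encodes the memory-associated factor TCF-1 (chromosome 11, 52246527 to 52283383), had 5 naive and 6 day 7 peaks. Among naive CBFβ peaks assigned to a gene, the most significant lay 30.9 kb from Tcf7 (chromosome 11, 52313377 to 52315034), with an enrichment of 39.0-fold in naive cells and 21.7-fold in the overlapping day 7 peak. Ccr7, the receptor that guides T cells into lymph nodes (chromosome 11, 99144199 to 99155077), had 7 naive peaks, 5 of which were missing from the day 7 list. No other gene had as many naive only peaks. It was followed by Emb, Scml4 and Tdrp with 3 each and Adam6b with 2, a number that 25 genes reached. Il7r, the receptor for the survival cytokine interleukin 7, had 1 peak in naive cells (chromosome 15, 9529529 to 9530093, 4.91-fold) and 0 at day 7. Lef1, the relative of Tcf7, had 7 and 6. The genes with the most day 7 only peaks were Prex1 with 10 and Akap13, Atxn1, Itpr1 and Zmiz1 with 9 each, all with long loci of 237 to 467 kb.

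Of the 14 fixed gene lists, 6 had CBFβ peaks near their members more often than other genes did in naive cells, and 10 at day 7. A gene counted as occupied when it was the nearest gene to a peak summit within 50 kb or when its span held the summit. In the naive list, 4127 of 20665 protein-coding genes were occupied (19.97%), but 17 of 20 memory and naive genes (adjusted p = 5.32e-09, Fisher's exact test, two-sided, over 56 tests). T cell receptor signalling genes (17 of 21), T cell transcription factors (24 of 37), cytokine receptors (13 of 19), trafficking genes (8 of 18) and glycolysis genes (8 of 14) also passed. Effector molecules (7 of 17, exact adjusted p = 0.0959), terminal effector genes (4 of 18), inhibitory receptors (2 of 10), interferon response genes (2 of 20) and cell cycle genes (6 of 22) did not. At day 7, 7524 genes were occupied (36.4%), and 10 lists passed. These were effector molecules (16 of 17, exact adjusted p = 2.96e-06), terminal effector genes (16 of 18), memory and naive genes (19 of 20), transcription factors (36 of 37), inhibitory receptors (9 of 10), cytokine receptors (16 of 19), trafficking genes (17 of 18), receptor signalling genes (20 of 21), cell cycle genes (14 of 22) and glycolysis genes (11 of 14). Interferon response genes (10 of 20, exact adjusted p = 0.362) did not pass. Genes of other tissues served as controls. The non-blood list had 0 of 15 occupied in both lists, below the background at day 7 (exact adjusted p = 0.00356), the B cell list had 0 and 2 of 10, and the myeloid list 1 and 3 of 12. Set against genes with at least 10 UMIs in the single-cell library, 5 of the 10 lists passed at day 7. The terminal effector, inhibitory receptor, cytokine receptor, cell cycle and glycolysis lists then did not, nor did trafficking and glycolysis genes in naive cells or glycolysis genes for T-bet. Random lists matched on locus size ended the call of trafficking genes in naive cells (permutation adjusted p = 0.0958). With only the stronger 50% of peaks, calls ended for glycolysis genes in naive cells and for T-bet and for cell cycle genes and inhibitory receptors at day 7, and effector molecules passed in naive cells.

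**Figure D2:**
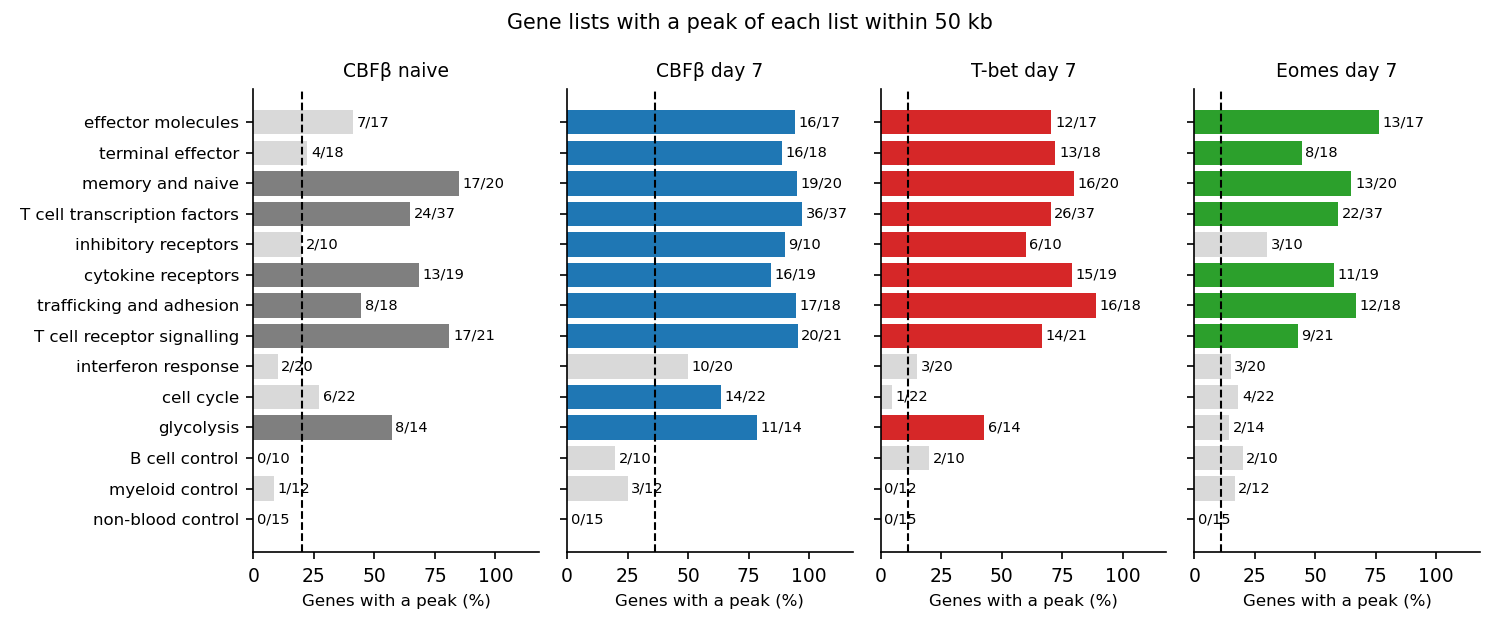
Share of the genes of each fixed list with a peak within 50 kb, in percent, for the 4 peak lists, with occupied genes over members beside each bar. Coloured bars passed Fisher's exact test above the background (adjusted p under 0.05), grey bars did not, and the dashed lines mark the share of all protein-coding genes, from 11.04% for Eomes to 36.4% for day 7 CBFβ.

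The second comparison set T-bet against Eomes, the 2 T-box factors of CD8 T cells, at day 7. Fewer than 50% of the peaks of either factor overlapped a peak of the other. Eomes peaks were found at 1562 of 3654 T-bet peaks (42.7%, 41.2 to 44.4), and T-bet peaks at 1520 of 3519 Eomes peaks (43.2%, 41.6 to 44.8). Random placement gave 0.283% and 0.3004%. Shared T-bet peaks were the stronger ones, with a median of 4.10-fold against 3.18-fold for the remainder. The lowest peak score was 159 in the T-bet list and 417 in the Eomes list, and how either list was cut is not stated.

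Several terminal effector genes carried T-bet peaks and no Eomes peak. T-bet occupied 13 of the 18 members of that list and Eomes 8, and 6 members had T-bet peaks without an Eomes peak: Klrg1, Zeb2, Cx3cr1, S1pr5, Klrc1 and Tbx21. Only Id2, an inhibitor of DNA-binding factors, had the reverse. The difference between the factors over this list did not pass an exact McNemar test, also chosen after the counts were seen (two-sided p = 0.125, adjusted p = 0.325 over 13 lists). Near Klrg1 (chromosome 6, 122270596 to 122282833) lay 4 T-bet peaks, the strongest of 6.46-fold at 122268951 to 122269671. The 4 T-bet peaks near Cx3cr1 (chromosome 9, 120048683 to 120068296) ranged from 1.92-fold, with a −log10 q of 0.659, to 5.35-fold. The 2 T-bet peaks in Zeb2, a repressor needed for terminal effector cells, were weak, at 2.43-fold and 2.61-fold. Memory and naive genes were occupied by both factors, 16 of 20 by T-bet and 13 by Eomes. Tcf7 had 4 T-bet and 5 Eomes peaks, and 4 sites around it were in all 4 lists. Ccr7 had 1 T-bet peak and 5 Eomes peaks, none of which overlapped the T-bet peak.

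**Figure D3:**
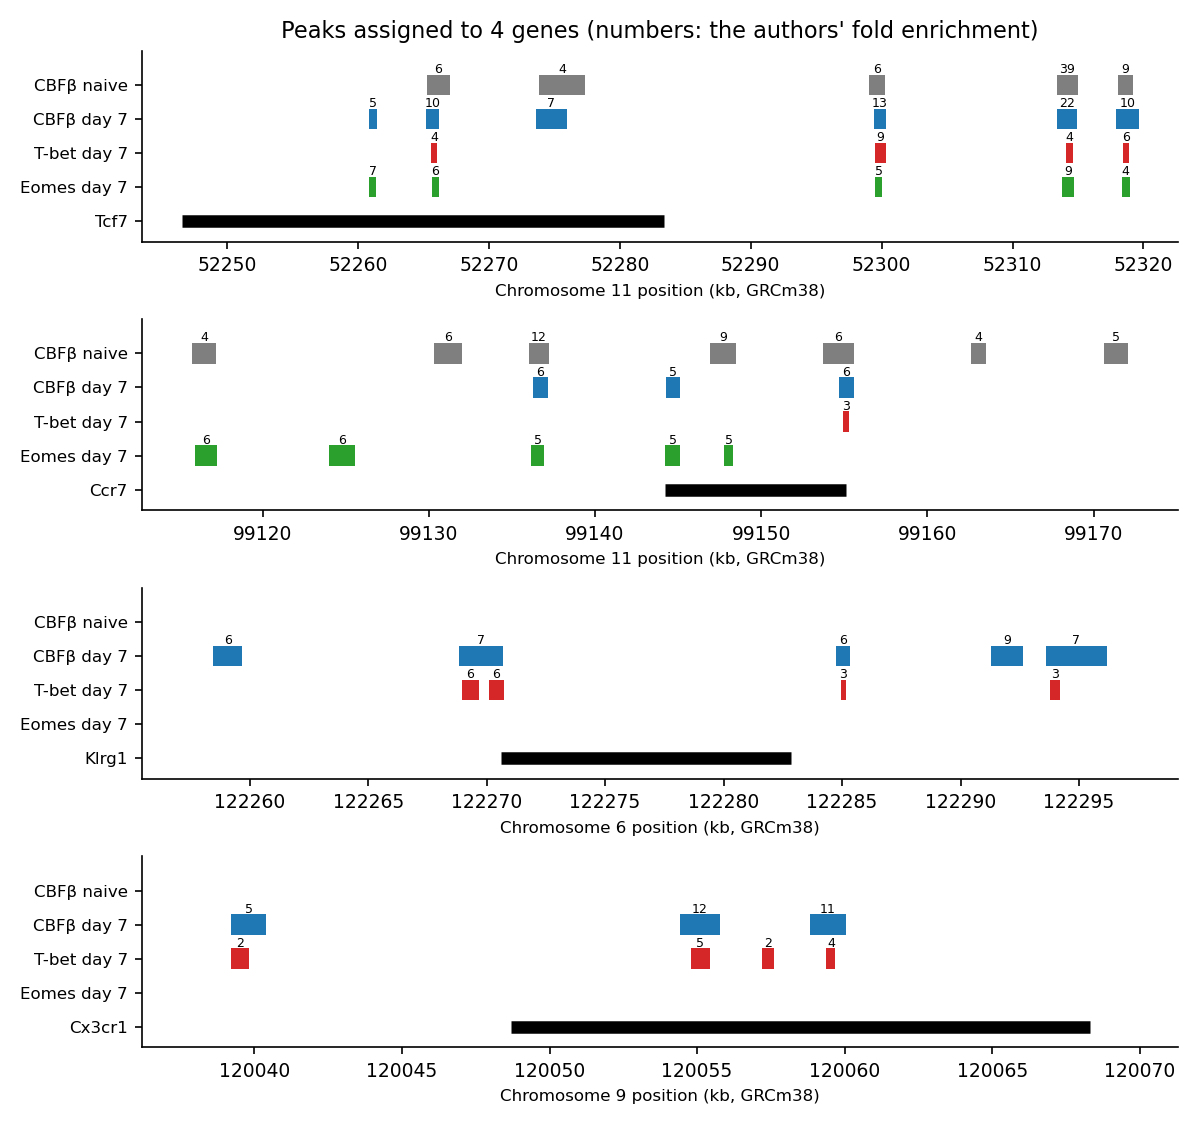
Peaks assigned to Tcf7, Ccr7, Klrg1 and Cx3cr1 in the 4 lists, drawn to scale against GRCm38 position in kb, with the authors' fold enrichment above each peak and the gene span in black. The genes were picked after their values were seen, and Klrg1 and Cx3cr1 show day 7 CBFβ and T-bet peaks, with 0 naive CBFβ and 0 Eomes peaks.

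T-bet peaks near effector genes were matched by Eomes peaks in most cases. Of the 17 effector molecules, 12 had peaks of both factors, and 1, Ctsw, had an Eomes peak without a T-bet peak. Ifng had 5 T-bet and 4 Eomes peaks, and Gzmb 4 and 3. T-bet also occupied 26 of 37 transcription factor genes, 15 of 19 cytokine receptors, 16 of 18 trafficking genes, 14 of 21 receptor signalling genes, 6 of 10 inhibitory receptors and 6 of 14 glycolysis genes. With effector, terminal effector and memory genes, these are the 9 lists that passed for T-bet (adjusted p from 4.50e-15 to 0.00550). Eomes occupied 22 transcription factor genes, 11 cytokine receptors, 12 trafficking genes and 9 receptor signalling genes, and 7 lists passed (adjusted p from 2.01e-11 to 0.000739). Inhibitory receptors (3 of 10, exact adjusted p = 0.139) and glycolysis genes (2 of 14) did not. Interferon response genes (3 of 20 for each factor) and cell cycle genes (1 of 22 for T-bet and 4 for Eomes) were not called for either. Among controls, 2 B cell genes had a T-bet peak and 2 an Eomes peak, 1 of them both, and 0 myeloid genes of T-bet and 2 of Eomes, and 0 non-blood genes of either.

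The most significant T-bet peaks assigned to a gene with an enrichment above 2-fold lay in Il18r1, a subunit of the interleukin 18 receptor (22.9-fold), and near H2az1, Ets1 and Slamf7. For Eomes they lay near Ifngr2, a subunit of the interferon gamma receptor (27.7-fold), near Ift57, and in Lif, Hemk1 and Gramd3 and in the overlapping spans of Gm19345 and Ceacam16. For CBFβ they lay near Tcf7, Calm2, Hnrnpa0 and Dad1 and in Gabpb1, Tsc22d2 and the overlapping spans of Ccdc77 and Kdm5a in naive cells, and at Calm2 (65.3-fold), Gabpb1, Dad1 and B4galt1 at day 7. Genes with the most T-bet peaks that were not Eomes peaks were Akap13, Ets1, Prex1, Prkch and Rora, with 6 each. Smchd1 had the most Eomes peaks that were not T-bet peaks, 7, of which 6 were wider than 5 kb. Ccr7, Cish, Foxp1 and Med12l followed with 5 each, a number that 7 genes reached.

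The third comparison asked where the T-box factors lay relative to CBFβ. T-bet was found at CBFβ sites more often than Eomes was. Day 7 CBFβ peaks overlapped 3125 T-bet peaks (85.5%, 84.3 to 86.6) and 2073 Eomes peaks (58.9%, 57.3 to 60.5). The share was 91.9% (90.4 to 93.1) for T-bet peaks that were also Eomes peaks and 80.8% (79.0 to 82.4) for those that were not. For Eomes peaks without T-bet it was 33.9% (31.9 to 36.0). The shares depend on the length of the lists. With each list reduced to the size of the smaller by significance, 47.4% of T-bet peaks and 32.9% of Eomes peaks overlapped CBFβ.

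Over all day 7 CBFβ peaks, a T-bet or Eomes peak was slightly more frequent at sites already bound in naive cells than at new sites. It was found at 1515 of the 4537 shared peaks (33.4%, 32.0 to 34.8) and at 2131 of the 6803 day 7 only peaks (31.3%, 30.2 to 32.4), an odds ratio of 0.910 (p = 0.0215, adjusted p = 0.0308 over 20 tests, Fisher's exact test, two-sided, over peaks and not over animals). Among peaks over 1 kb from gene ends, a setting chosen after the data were seen, the gap was wider, with 50.4% and 42.5% (exact p = 1.62e-08). With overlap defined by summits within 200 bp the gap was 0.71 percentage points and did not pass (exact p = 0.431). With the stronger 50% of each list, day 7 only peaks were higher by 6.18 points, and with equal numbers of peaks by 19.5. Both settings also cut the naive list, so day 7 only peaks can there overlap a weaker naive peak. The direction also turned once peaks of like strength were compared. In the strongest of 4 equal bins of the day 7 CBFβ peaks by −log10 q, 521 of 690 day 7 only peaks had a T-box peak (75.5%, 72.2 to 78.6) against 1032 of 2145 shared peaks (48.1%, 46.0 to 50.2, exact adjusted p = 2.55e-36). In the third bin the shares were 43.9% and 23.9%, and in the second 26.9% and 16.7%. In the weakest bin they were 15.3% and 13.2% (exact adjusted p = 0.424). T-bet alone and Eomes alone gave the same order in the 3 upper bins. Over all peaks, T-bet peaks were at 27.6% of shared and 25.6% of day 7 only peaks (exact adjusted p = 0.0291). For Eomes peaks these shares were 18.2% and 17.9% and did not differ by the test (exact adjusted p = 0.719). Bins of −log10 q were chosen after the data were seen, since 56.3% of the day 7 CBFβ peaks tied at the highest score. The planned split at that score also turned the direction, with day 7 only peaks higher by 5.13 percentage points below it and by 9.30 at it.

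**Figure D4:**
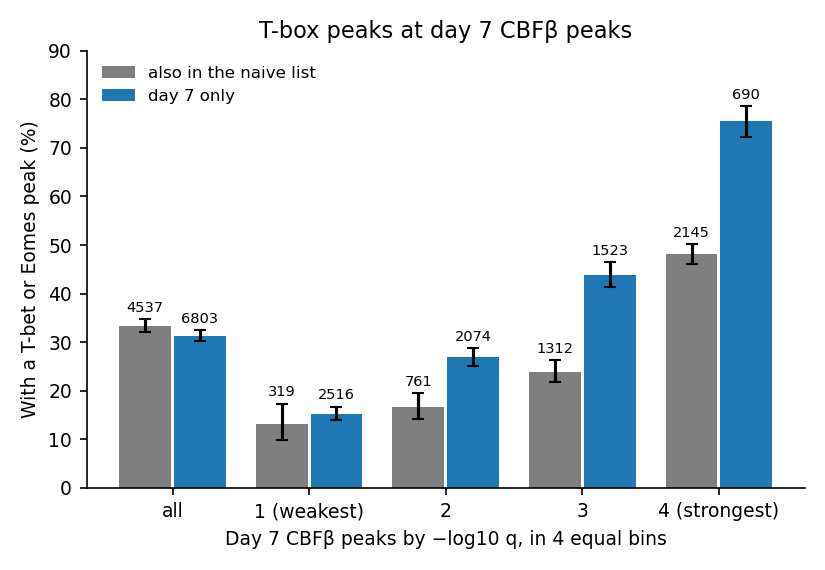
Share of day 7 CBFβ peaks with a T-bet or Eomes peak, in percent with 95% Wilson intervals, for peaks also in the naive list and for day 7 only peaks, over all peaks and within 4 equal bins of −log10 q. Numbers above the bars are CBFβ peaks, and the difference reaches 75.5% against 48.1% in the strongest bin.

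The single-cell library described day 7 cells of B6/Spret F1 mice. After removal of 154 cells with fewer than 500 genes and of 5 cells with the markers of another type, 2761 cells with 10249845 UMIs remained, with a median of 3037 UMIs per cell. They were CD8 T cells, most of them outside the 1 low-cycling cluster. Cd8b1 reached 1461 CPM, counts scaled to a common UMI total (exact interval 1438 to 1485), and Cd4 2.73 (1.82 to 3.95), and 3 of the 4 clusters were marked by genes of the cell cycle or of protein folding. Cluster 1, with 979 cells (35.5%, 33.7 to 37.3), was the only one with low levels of cycling genes. These genes were at 309 CPM there and at 2363, 5965 and 5676 in clusters 2, 3 and 4. The 5 leading genes of cluster 1 were Mxd4, Bcl2, Ypel3, Eva1b and Ccl5, among them Bcl2, which protects from cell death. Cluster 2, with 898 cells, was marked by Ebna1bp2, Hspa5, Mcm6, Dtl and Pdia6. Cluster 3, with 731 cells, was marked by the histone genes Hist1h2ae, Hist1h1b, Hist1h1a and Hist2h2ac together with Esco2. Cluster 4, with 153 cells, was marked by Tnfaip8l1, Gpsm2 and the mitotic regulators Cdc20, Cdc25c and Ccnb1.

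Tcf7, Il7r and Id3 transcripts were scarce and highest in the low-cycling cluster. Tcf7 reached 34.4 CPM there (27.2 to 43.0) against 3.5 to 6.3 in the other 3, and Il7r 42.4 (34.3 to 51.8) against 3.2 to 14.1. Id3, another memory-associated regulator, was at 34.4 and at most 4.4. Klf2 and Lef1, members of the memory and naive list, were more abundant and less uneven, at 1172 and 238 CPM there against 837 to 922 and 153 to 184. Ccr7 was at 1.66 over all cells. Klrg1 differed little, from 140 to 169 CPM over the clusters, as did Tbx21, from 96.2 to 138, and Eomes, from 40.9 to 55.2. Over all cells, Tbx21 was at 127 and Eomes at 42.8, Cbfb at 134 and its partner Runx3 at 186.

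The fourth comparison set cells with a Klrg1 UMI and no Il7r UMI against cells with an Il7r UMI and no Klrg1 UMI, the textbook markers of terminal effector and memory precursor cells. Klrg1 cells had more Gzma, Zeb2 and Cx3cr1 transcripts, and Il7r cells more of Bcl2, Slamf6 and Ltb. Gzma, which encodes granzyme A, was 2.26 times as high in Klrg1 cells (95% interval 1.97 to 2.59), Zeb2 2.59 times (1.84 to 3.76) and Cx3cr1 1.86 times (1.40 to 2.53). Bcl2 was at 0.387 of its level in Il7r cells (0.291 to 0.521), Slamf6, a receptor of memory precursors, at 0.511 (0.424 to 0.621), and Ltb, which encodes lymphotoxin beta, at 0.353 (0.2996 to 0.419). The groups held 903 and 104 cells, with medians of 3789 and 2738 UMIs. A further 33 cells had both markers and 1721 neither. A Klrg1 UMI was seen in 33.9% of the kept cells (exact interval 32.1 to 35.7) and an Il7r UMI in 4.96% (4.18 to 5.84), at a median of 3037 UMIs. In the 5 cells of another type, at a median of 2969 UMIs, each was seen in 0 cells, which allows a share of up to 52.2%, so background from free RNA is poorly bounded. The groups also differed in division, with 25.1% of Klrg1 cells and 56.7% of Il7r cells in the low-cycling cluster.

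By gene list, memory and naive genes were lower in Klrg1 cells, with summed UMIs at 0.782 of the level in Il7r cells (0.732 to 0.836) and a median ratio of 0.755 over 11 measured members, at percentile 0.02 of random lists matched on expression. Bcl2, Slamf6 and Foxo1 (0.626, 0.434 to 0.929) led, while Eomes itself was at 1.73 with an interval that spans 1 (0.859 to 4.08). Effector molecules split. Ccl3 (1.91), Ccl4 (1.99), Serpinb9 (1.92) and Gzmb (1.41, 1.27 to 1.58) had ratios above 1, but Ccl5, the most abundant, was at 0.904 (0.881 to 0.927), Srgn at 0.782 (0.683 to 0.899) and Ctsw at 0.772 (0.671 to 0.891). The median ratio of this list was therefore 1.16, at percentile 95.7, while the summed ratio was 0.989 (0.968 to 1.01). Terminal effector genes had a median of 0.956 and a summed ratio of 1.06 (1.04 to 1.09), on opposite sides of 1. Zeb2, Cx3cr1 and Lgals1 were above 1 and Itgb1 (0.786, 0.687 to 0.902) and S100a6 (0.845, 0.802 to 0.891) below. Tbx21 was at 1.40 (0.994 to 2.03). Inhibitory receptors had a median of 0.733 and a summed ratio of 0.719 (0.602 to 0.865), with Lag3 at 0.496 (0.372 to 0.673). Cytokine receptors had a summed ratio of 0.789 (0.720 to 0.865), with Il15ra at 0.276 (0.153 to 0.530) and Tgfbr2, a receptor of the cytokine TGF beta, at 0.429 (0.288 to 0.657).

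Cell cycle genes were the list furthest above 1, with a summed ratio of 1.71 (1.60 to 1.82), a median of 1.81 and a percentile of 100. Tyms, which makes thymidylate for DNA synthesis, was at 3.55 (2.20 to 6.13), Top2a at 2.07 (1.75 to 2.47) and Mki67 at 1.90 (1.59 to 2.29). The summed ratios of the remaining lists were 0.951 (0.910 to 0.995) for T cell transcription factors, 0.875 (0.834 to 0.918) for trafficking genes, with Cxcr6 at 0.640 (0.537 to 0.769) and Ccr2 at 0.699 (0.532 to 0.935), 0.944 (0.912 to 0.977) for receptor signalling, 0.722 (0.650 to 0.804) for interferon response and 1.16 (1.08 to 1.24) for glycolysis. Their median ratios were 0.954, 0.824, 0.920, 0.845 and 1.10. Low percentiles among random lists were not particular to memory and naive genes, with trafficking genes at 0.01, cytokine receptors at 0.08, inhibitory receptors at 1.22 and receptor signalling at 1.25. The 3 control lists had at most 1 measured member each. Among all genes with at least 200 UMIs, the 10 highest ratios whose interval excluded 1 belonged to Tex30 (5.12, 1.98 to 18.9), Kpna3, Agfg2, Mid1ip1, Sgo2a, Tyms, H1f1, Spag5, Prim1 and As3mt. Il7r cells held few UMIs of these 10 genes, from 4 for Tex30, Kpna3 and Mid1ip1 to 17 for Tyms. Intervals were not adjusted for the 3606 genes screened. Sgo2a and Spag5 act in chromosome segregation and Prim1 in DNA replication. The 10 lowest were Ltb, Bcl2, Ikzf2, Emb, Traf1, Trim12a, Sting1, Evl, Gramd1a and Lag3, from 0.353 to 0.496.

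**Figure D5:**
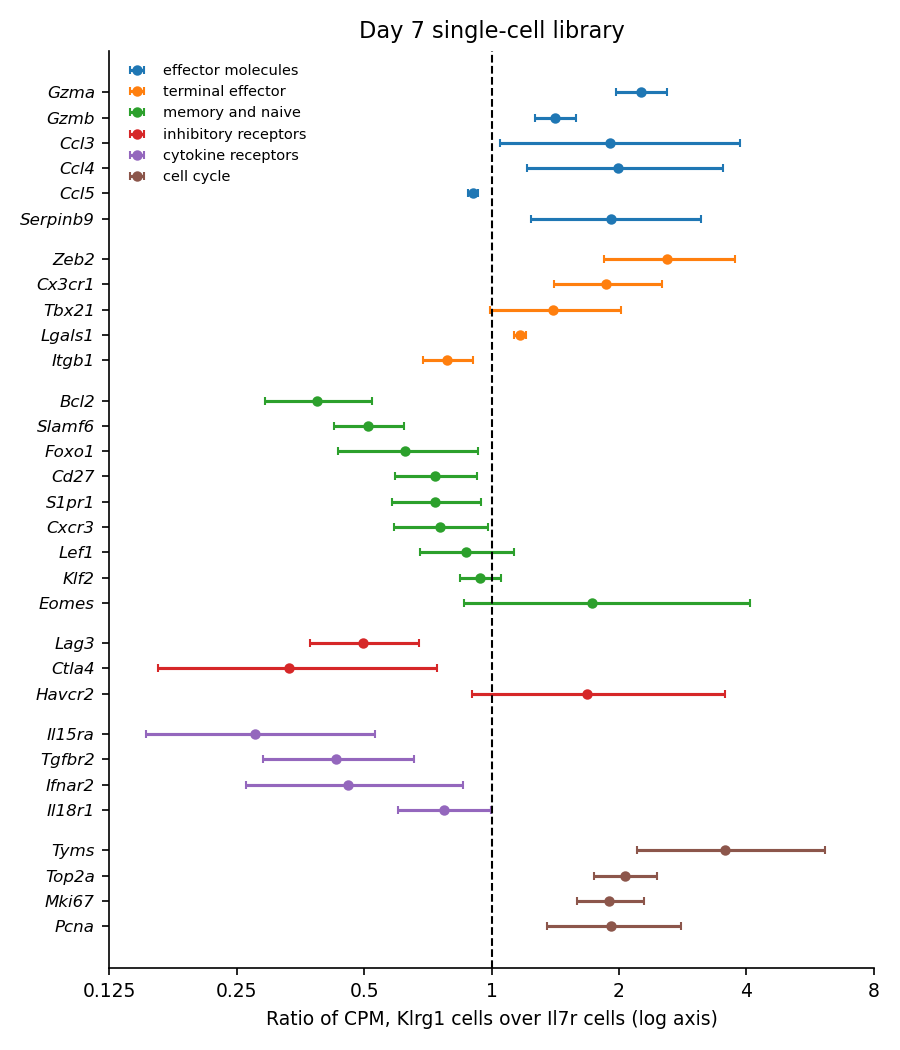
Ratio of CPM, between Klrg1 cells and Il7r cells on a log axis, with exact 95% intervals that cover counting error, for members of 6 gene lists picked after their values were seen. Zeb2 and Gzma lie above 1, and Bcl2, Slamf6, Lag3 and Tgfbr2 below.

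Several of these values differed within the low-cycling cluster. In that cluster alone, with 227 Klrg1 cells and 59 Il7r cells, Zeb2 was at 6.25 (3.34 to 13.2), Gzma at 5.65 (4.29 to 7.58), Cx3cr1 at 3.39 (2.15 to 5.64) and Tbx21 at 2.69 (1.30 to 6.43). There, effector molecules had a summed ratio of 1.41 (1.37 to 1.45). The trafficking list was at 1.07 (0.993 to 1.15), cytokine receptors at 0.964 (0.834 to 1.12), cell cycle genes at 1.27 (0.978 to 1.68) and Tyms at 2.82 (0.692 to 24.7), each with an interval that spans 1. With at least 2 UMIs of the marker, 389 and 23 cells remained. Cell cycle genes were then at 3.02, Cx3cr1 at 5.29 (2.05 to 19.5), Tbx21 at 2.32 (0.985 to 7.21), Ltb at 0.195, Lag3 at 0.225 and Bcl2 at 0.474 (0.2496 to 1.01). The library is 1 sample, and cells are not replicates, so none of these ratios has an error between animals.

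The last comparison asked whether genes near peaks of a factor differed between Klrg1 and Il7r cells. Shifts were small, and none was outside the random range once cycling clusters were left out. Fewer genes were measured there, and the random ranges were wider. Over all 6948 measured genes the median ratio was 1.02. In all kept cells, genes with T-bet peaks were slightly lower in Klrg1 cells, with median ratios of 0.973 for 734 measured genes with T-bet only (percentile 0.01 of random lists matched on expression) and 0.968 for 788 genes with both T-box factors (percentile 0, the lowest that 10000 lists can give). Genes with Eomes only (446, median 1.02, percentile 44.0) lay within the random range. Genes with CBFβ peaks at both times (2849) had a median of 0.997, also at percentile 0. Genes with a CBFβ peak in naive cells and no day 7 peak (87) were at 1.01, within the random range. Genes with the reverse (2074) were at 1.03, also within it. Klrg1 and Il7r cells differ in division, as given above. Without the cycling clusters, an alternative chosen after the data were seen, the median was 1.04 for T-bet only (290 genes, percentile 90.5), 1.02 for both T-box factors (374 genes, percentile 59.4) and 0.990 for CBFβ at both times (1132 genes, percentile 3.5). For CBFβ at both times, the median log2 ratio without cycling clusters was −0.0145, with a random range of −0.0173 to 0.0430. In all kept cells it was −0.00389, with a random range of 0.0171 to 0.0494. The lost call of this class therefore does not show that its shift was smaller. The peak classes pool B6/Cast F1 peaks with B6/Spret F1 cells, so strain differences were not separated.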

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

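The tests of explanations below were chosen after the result each concerns was seen, except the ratios in the low-cycling cluster and at 1 depth, which were planned as alternatives. Of the cells past the filters, 5 had markers of another cell type, 3 of B cells, 1 of myeloid cells and 1 of neutrophils, and they stood out because the comparisons did not use them. They held 70 Lyz2 UMIs, against 0 in the 2761 kept cells, 203 of Cd74, against 73, and 123 of S100a9, against 24.

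New CBFβ sites carried T-box peaks less often than old ones over all peaks, and more often among peaks of like strength. The odds ratio pooled over 4 bins of −log10 q was 2.36 (2.12 to 2.61), on the other side of 1 from the unadjusted 0.910, so the difference in strength between the classes is a candidate explanation for the first direction. Shared sites lie more often at gene ends, but among peaks over 1 kb from them the pooled odds ratio was 1.87 (1.63 to 2.15), which argues against gene ends as the whole cause of the second direction. Recruitment of T-box factors together with CBFβ after infection may account for it and stays untested, as do differences in depth and in the number of samples between the lists.

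Of the Eomes peaks, 163 were wider than 5 kb, and the widest, in Ckap5, spanned 55427 bp. A single one of them, 0.613% (0.108 to 3.39), overlapped a peak of another list, which argues against repeated sequence that every antibody would pull down. Of their summits, 99.4% lay inside a gene, against 51.7% for narrower Eomes peaks, and the 104 genes under them had a median of 1166 UMIs in the single-cell library, at percentile 100 of random genes of like length, whose highest median was 239.5. The random genes came from all protein-coding genes, with or without a peak, and those without a column counted as having no UMIs. Genes under narrower Eomes peaks were not compared, so a high level is not shown to be particular to the wide peaks. Signal along transcribed genes is a candidate explanation, whether from the antibody, the background sample or Eomes itself, and no biological explanation was tested.

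Memory and naive genes were lower in Klrg1 cells than in Il7r cells, at 0.782 (0.732 to 0.836). Within the low-cycling cluster the ratio was 0.865 (0.784 to 0.957). Cell cycle genes were still at 1.27 (0.978 to 1.68) there, so the cluster may not remove the difference in division. Whether cell division is the whole cause of the lower sum was therefore not decided, and it may account for part. The list's ratio of 0.865 leans on Bcl2 (0.445) and Slamf6 (0.463). Those 2 genes held 46 and 88 of the list's 513 UMIs in Il7r cells there, against 80 and 159 of 1734 in Klrg1 cells. A remaining difference was not shown for the other members. With cells thinned to 1 depth, the ratio of the whole list was 0.776 (0.703 to 0.859). The groups were set at full depth, and the ratio was already scaled to total UMIs. Thinning therefore cannot decide whether depth, which bears on the cells that show a marker UMI, plays a part. A difference between terminal effector and memory precursor cells stays open as a hypothesis, as does free RNA in the droplets, which was not tested.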

How the results depend on the processing

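The alternatives with bins of −log10 q, without Eomes peaks over 5 kb, with an enrichment of at least 2-fold, over 1 kb from gene ends and, for peak classes, without cycling clusters were chosen after seeing the data. Of 185 alternative values over 34 results, 131 kept their direction and call, stayed within counting error or, for counts of lists, within 1.5 times. A further 41 moved by more, 4 lost their call and 9 reversed in estimate, whether or not the reversed value itself passed. Except where stated, the cause was not tested. Sharing fell where overlap needed summits within 200 bp. It was then 87.1% for naive in day 7 CBFβ, 37.8% for the reverse, 39.8% for T-bet in Eomes, 41.4% for the reverse, 73.8% for T-bet in CBFβ and 53.3% for Eomes in CBFβ. With the stronger 50% of each list, the first pair was 89.5% and 38.9% and the last pair 73.7% and 53.9%. With equal numbers of peaks these were 65.2%, 64.8%, 47.4% and 32.9%. Without Eomes peaks over 5 kb, Eomes in T-bet was 45.3% and Eomes in CBFβ 61.7%. The difference in T-box share, day 7 only minus shared CBFβ peaks, was −2.07 percentage points and −7.94 over 1 kb from gene ends. With summits it was −0.71 and lost its call. It reversed to 6.18 with the stronger 50% and 19.5 with equal numbers, both of which also cut the naive list. It was 5.13 below and 9.30 at the highest score. In the 4 bins it was 2.096, 10.2, 19.99 and 27.4, and the weakest bin did not pass (Fisher's exact test, adjusted p = 0.424). With a background of genes with at least 10 UMIs, 5 lists passed for day 7 CBFβ, 4 of 6 for naive CBFβ and 8 of 9 for T-bet. With locus-matched lists, 5 passed for naive CBFβ, and with the stronger 50%, 8 each for day 7 CBFβ and T-bet. For naive CBFβ 1 list was then exchanged. Without cycling clusters, summed ratios were 0.865 for memory genes, 1.27 for the cell cycle, 0.964 for cytokine receptors, 1.41 for effector molecules and 1.27 for terminal effector genes. The trafficking list was then at 1.07 (0.993 to 1.15), reversed in estimate but with an interval that spans 1. Thinned to 1 depth, the cell cycle was at 2.03, effector molecules at 1.04 and terminal effector genes at 1.10. With at least 2 UMIs of the marker, the cell cycle was at 3.02, cytokine receptors at 0.693, effector molecules at 0.961, terminal effector genes at 1.140 and trafficking genes at 0.918, from 23 Il7r cells. The low-cycling share was 37.6% at resolution 0.3 and 42.3% with 1000 variable genes. The interferon response ratio stayed within its interval and Eomes kept 7 lists. The percentile of Eomes only ran from 6.25 to 69.6, within the random range. Without cycling clusters, 3 peak classes lost their call, from fewer genes and cells. T-bet only was then at percentile 90.5 and both T-box factors at 59.4, with median ratios that turned from below to above 1. CBFβ at both times was at 3.50, with a median that stayed below 1. Doublet calling found 0 cells, so that setting changed nothing, and neither did a restriction to autosomes, where all peaks lie. No paired analysis was possible because the files hold no columns per replicate, although the labels share replicate numbers between groups. For the same reason the alternatives for per-replicate and allelic values were not run, and those for motifs were not run for want of a genome. The Il7r group holds 340501 UMIs in 104 cells, against 4105160 in the 903 Klrg1 cells.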

Other observations

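RUNX genes, whose products bind DNA together with CBFβ, were themselves among the genes with many CBFβ peaks at day 7. Runx1 went from 4 naive to 12 day 7 peaks, Runx2 from 2 to 9 and Runx3 from 3 to 9, while Cbfb had 1 in each. The 3 RUNX loci are longer, at 305, 369 and 125 kb against 61.2 kb for Cbfb. The day 7 list is also longer than the naive list, and these counts were not corrected for either. All 3 RUNX genes also had T-bet and Eomes peaks, with 5 and 8 at Runx1, 7 and 3 at Runx2 and 4 and 5 at Runx3. Tbx21, the gene of T-bet, had 4 CBFβ peaks at day 7, 1 T-bet peak and 0 Eomes peaks, and the Eomes gene had 2 CBFβ peaks and no peak of either T-box factor. In the single cells, Cbfb was at 67.1 CPM (56.9 to 78.7) in the low-cycling cluster and at 171 in the cluster marked by histone genes, while Runx3 stayed between 177 and 196. These genes were singled out after their values were seen.

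T-bet and Eomes peaks lay mostly away from gene ends. Of T-bet peaks, 22.7% (21.4 to 24.1) had a summit within 1 kb of the end of a gene span, and of Eomes peaks 12.3% (11.3 to 13.4), against 58.1% (56.7 to 59.4) of naive and 46.0% (45.1 to 46.9) of day 7 CBFβ peaks.

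Some of the most significant peaks had little enrichment. The first in all 4 lists was on chromosome 2 near position 98666424, at 1.58-fold to 1.82-fold with −log10 q of 5827 to 9867. Of the 10 most significant peaks, 2 in the naive CBFβ list, 4 in the day 7 CBFβ list, 5 in the T-bet list and 3 in the Eomes list were below 2-fold. Over whole lists, 9, 5, 53 and 10 peaks were below 2-fold, and 99 T-bet peaks had a −log10 q under 2.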
